A study of Homo sapiens with 30 samples.

How the data were processed

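The series holds 30 RNA libraries of A549 cells, made after 24 h with an extract of Soshiho-tang, Yijin-tang, Okbyeongpung-san or Soyo-san at 500, 100 or 20 µg/mL, or with vehicle. Per the labels the libraries were made with a directional messenger RNA kit and read as 100 bp pairs. The deposited values are expected counts per gene, which the authors made by read mapping and RSEM estimation. Per the submitters' processing notes the tools were FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3, with genome builds named as hg38 and GRCh38. The annotation release and the strand setting of the counting are not stated, so genes that overlap another gene, and near-identical paralogs and pseudogenes, have uncertain assignments. The table held 60675 Ensembl identifiers, 30 columns that matched the libraries and 30 empty columns, which were left out. In each library between 9.09% and 11.6% of the values were not whole numbers, and all values were rounded before fitting. No library was a duplicate of another, which was checked on the counts. Of the identifiers 56558 matched the table of gene names, 41209 with a symbol, and 57055 were found in GENCODE release 29, which gave positions, transcript lengths and gene types on GRCh38.

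Other treatments and assays that the series text mentions were not analysed here. Vehicle is 0.1% DMSO per the labels and 2% DMSO in the series text, and the labels were followed; no value here can decide between them. Library titles carry batch D for 6 libraries and batch E for the others, and what the letters stand for is not stated.

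Libraries held between 19833144 and 38008463 counts, and 34894 genes had a total above 0. The common dispersion over fitted libraries was 0.00474, a biological coefficient of variation of 6.89%. Given means are of CPM, counts scaled to TMM-adjusted library totals, with the standard deviation (SD) over libraries.

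The 27 libraries of the 10 groups with at least 2 libraries were fitted together with edgeR 4.0.16 in R 4.3.3, so that small groups share an estimate of spread. Counts were normalised with TMM, genes with low counts were removed with filterByExpr, and glmQLFit and glmQLFTest gave the quasi-likelihood F test for each comparison. This left 17459 genes, 15573 of them with a symbol. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, and every adjusted p of a single gene in the text comes from this test. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. The 12 comparisons were fixed before the data were examined: each dose of the 3 replicated extracts against vehicle, Soshiho-tang against Yijin-tang at 500 µg/mL, and 500 against 20 µg/mL of each of these 2 extracts. The gene lists, the naming rule and the first set of other settings were fixed at the same time. Comparisons of 500 with 20 µg/mL of Okbyeongpung-san, of 100 with 20 µg/mL, of Soshiho-tang with Yijin-tang at lower doses, and of dose effects between extracts were added after the data were seen.

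Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. The same test with a correlation estimated from the residuals is given beside it, and fry was run as an alternative. Counts of members that rose or fell use the calls over all genes tested, and counts adjusted over the list alone repeat the adjustment within the list. The 36 lists, written from textbook knowledge, covered targets of the aryl hydrocarbon receptor, NRF2, the liver X receptor, p53, NF-kappa-B, interferon, hypoxia-inducible factors, the glucocorticoid receptor and FOXO; xenobiotic conjugation, cholesterol, fatty acid synthesis, fatty acid oxidation, glycolysis and metallothionein genes; the integrated stress response, endoplasmic reticulum chaperones and heat shock; DNA replication, mitosis, histones, ribosomal proteins, ribosome biogenesis and the respiratory chain; lysosome, TGF-beta, epithelial, alveolar, mucin and immediate early genes. Mitochondrially encoded messenger RNAs and abundant non-coding RNAs served as signs of RNA quality, and immune, fibroblast, hepatocyte and endothelial markers as signs of other cells. Of these, 34 had at least 3 measured members and were tested; the immune and endothelial lists had fewer.

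Named genes were chosen by rule. For each extract at 500 µg/mL against vehicle, and for Soshiho-tang against Yijin-tang at 500 µg/mL, the rule took up to 8 higher and 8 lower genes with the largest fold changes among called genes with a symbol, a mean log2 CPM of at least 2 and all libraries of one group above all of the other. For lower doses and for 500 against 20 µg/mL of Soshiho-tang and Yijin-tang it took 3 in each direction. For the added comparison of 500 with 20 µg/mL of Okbyeongpung-san it took 8. It added up to 4 members of each called list, and CYP1A1, CYP1B1, NQO1, HMGCS1, CDKN1A, GDF15 and ASNS in every comparison. The text gives a selection of these genes. Genes of the added comparison of dose effects, and genes given to describe single libraries, were chosen after their values were seen.

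Soyo-san has 1 library per dose, so its values are log2 CPM (prior count 1) minus the vehicle mean, for 10997 genes with a mean of at least 5 CPM, and list medians were set beside 10000 random lists of the same size matched on expression. The similarity of the Soshiho-tang and Yijin-tang responses was set beside 20 simulations of unchanged groups that share the vehicle libraries. The fit was tested on simulated data with 200 changed genes among 17295. At 2-fold, 95.5%, 94.0% and 88.1% were recovered for the group sizes of Soshiho-tang, Yijin-tang and Okbyeongpung-san at 500 µg/mL. At 1.5-fold these were 86.6%, 80.6% and 73.1%, and 8, 12 and 6 unchanged genes were called. Every simulated group had the same spread per gene, and no library stood apart. The real groups differed in spread, most of all Okbyeongpung-san at 500 µg/mL, so these rates do not show how the fit does there.

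Other settings fixed in advance were RLE size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, only the 2 groups in the fit, a replicate block, each library left out in turn, camera with an estimated correlation, fry, and other limits on CPM and the prior count for Soyo-san. Settings chosen after seeing the data were the 20 µg/mL libraries in place of vehicle, 1 surrogate variable from sva 3.50.0, an offset for a trend over transcript length and GC in each library (17328 genes had a length), and libraries thinned to the lowest total.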

Results

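RNA was sequenced from A549 cells, an established line from a human lung carcinoma that is used as a model of the lung epithelium. The cells had been kept for 24 h with an ethanol extract of 1 of 4 herbal formulas of Korean medicine, or with the solvent dimethyl sulfoxide (DMSO) alone, here called vehicle. Vehicle had 3 libraries. Soshiho-tang and Yijin-tang had 3 libraries at each of 500, 100 and 20 µg/mL. Okbyeongpung-san had 2 libraries per dose and Soyo-san had 1, so Soyo-san is given as values with no test. The 30 libraries held between 19833144 and 38008463 counts. Library titles put 6 libraries in batch D, namely the 3 Soyo-san libraries and replicate 3 of Okbyeongpung-san at each dose, and the remaining libraries in batch E. The labels give the vehicle as 0.1% DMSO and the series text as 2% DMSO. The labels do not say whether replicates were separate cultures, so the p-values below measure the spread between libraries, which can be technical.

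The 3 vehicle libraries stood apart from the treated libraries in depth and in mitochondrial RNA. Vehicle libraries held 19833144 to 22327652 counts, fewer than any treated library, the lowest of which held 24560759. Mitochondrially encoded messenger RNAs made up 14.2% ± 0.262 of their counts (SD, n = 3), and between 8.99% and 13.1% in the 27 treated libraries. On the first principal component of the 17459 genes tested, which held 14% of the variance, vehicle libraries lay at −40.6 ± 0.610. Single transcripts differed as well. MT-ATP8, a mitochondrial subunit of ATP synthase (chromosome M, 8366 to 8572), was at 1840 ± 260 CPM (counts scaled to the library total) in vehicle and at 507 ± 262 CPM in the 27 treated libraries, of which replicate 2 of Okbyeongpung-san at 500 µg/mL, at 1748 CPM, lay within the vehicle range. NDUFB1, a subunit of respiratory complex I, was at 29.3 ± 1.26 CPM in vehicle and higher in each treated library, up to 78.0 CPM. TUBA1B-AS1, a non-coding RNA that overlaps TUBA1B on the opposite strand and has an uncertain assignment, was at 42.85 ± 17.1 CPM in vehicle. In the 27 treated libraries it was at 0.289 ± 0.340 CPM, and at most at 1.72 CPM. ENSG00000279364, a gene without a symbol, had 0 counts in each vehicle library and 92 to 519 counts in the treated libraries. Among the 9 comparisons of an extract with vehicle, 184 genes were higher and 207 lower in all 9, and with a length and GC offset 212 and 442. Their median transcript lengths were 1626 and 4683 bases, beside 2924 for all genes tested. Each dose of 500 µg/mL was also compared with 20 µg/mL of the same extract, a comparison that does not use the vehicle libraries.

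A second departure was replicate 2 of Okbyeongpung-san at 500 µg/mL, which held 38008463 counts with a mitochondrial share of 13.1%, against 27540408 counts and 9.73% in replicate 3. The chi-square per degree of freedom between these libraries was 42.4, between vehicle libraries it was 2.07 to 2.21, and between replicates of the other treated groups 2.81 to 19.25.

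**Figure D1:**
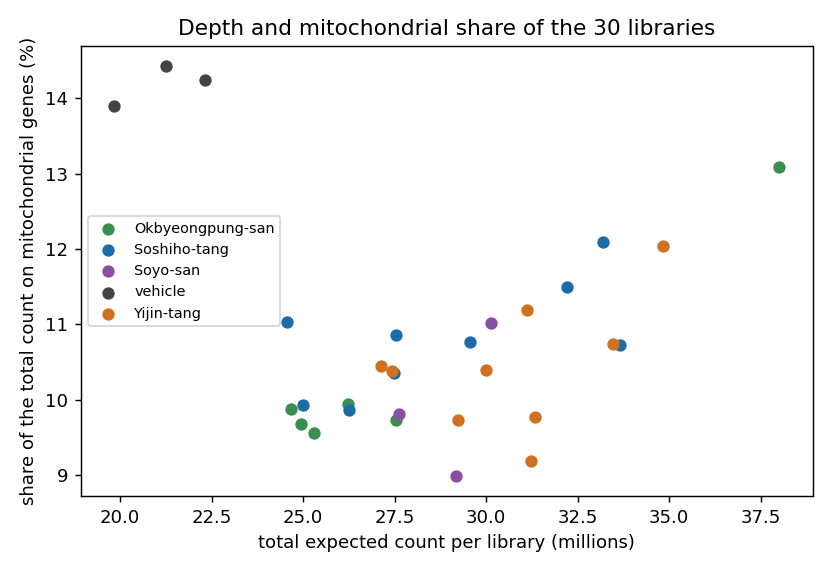
Total count per library, on an axis scaled as its label states (x axis), against the percentage of counts from mitochondrially encoded messenger RNAs (y axis), 1 point per library for all 30 libraries, coloured by group. The 3 vehicle libraries sit at 19833144 to 22327652 counts and 13.9% to 14.4%, and replicate 2 of Okbyeongpung-san at 500 µg/mL at 38008463 counts and 13.1%.

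Soshiho-tang at 500 µg/mL was compared with vehicle to find the transcripts that differed at its highest dose. Genes of the amino acid and integrated stress response, targets of the transcription factor ATF4, rose together: 18 of 20 measured members rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 fold change of 1.14 (camera adjusted p = 3.81e-24; adjusted p = 0.00056 with an estimated correlation). STC2, which encodes the secreted glycoprotein stanniocalcin 2 (ENSG00000113739, GRCh38 chromosome 5, 173314713 to 173329503, minus strand, protein-coding in GENCODE release 29), went from 20.7 ± 1.25 to 122 ± 13.2 CPM (SD, n = 3 and 3), a log2 fold change of 2.56 ± 0.07 (SE). TRIB3, a pseudokinase induced by stress (ENSG00000101255, chromosome 20, 362835 to 397559, plus strand), rose by 2.12 ± 0.09. ASNS, asparagine synthetase (ENSG00000070669, chromosome 7, 97852118 to 97872542, minus strand), rose by 1.45 ± 0.06, and PSAT1, an enzyme of serine synthesis, by 1.13 ± 0.05. Outside the list, NIBAN1, a stress-responsive gene (ENSG00000135842, chromosome 1, 184790724 to 184974550, minus strand), rose from 5.63 ± 1.00 to 46.1 ± 7.67 CPM, by 3.04 ± 0.14 (adjusted p = 1.45e-13). TSC22D3, a glucocorticoid-induced leucine zipper gene, rose by 1.85 ± 0.10.

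Chaperones of the endoplasmic reticulum rose in the same libraries, while cytosolic heat shock genes fell. Of 16 endoplasmic reticulum genes 12 rose and 0 fell (14 and 0 adjusted over the list alone; median 0.38; adjusted p = 0.00156 with an estimated correlation), among them HSPA5, the main chaperone of that compartment, by 0.65 ± 0.04, and HERPUD1, which takes part in protein degradation there, by 0.85 ± 0.06. Of 13 heat shock genes 12 fell and 0 rose (median −0.56; adjusted p = 0.0159 with an estimated correlation). HSP90AA1, an abundant cytosolic chaperone, fell by 0.80 ± 0.05. The near-identical paralogs HSPA1A (chromosome 6, 31815464 to 31817946) and HSPA1B, between which reads cannot be assigned with certainty, fell by 1.37 ± 0.12 and 1.40 ± 0.13. NR4A3, an orphan nuclear receptor of the early response (ENSG00000119508, chromosome 9, 99821855 to 99866891, plus strand), fell from 8.80 ± 0.191 to 3.54 ± 0.119 CPM, by 1.31 ± 0.11.

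Proliferation genes were lower with Soshiho-tang at 500 µg/mL. Each of the 24 genes of DNA replication and each of the 25 genes of mitosis fell, with medians of −0.33 and −0.50, and the adjusted p was 0.000927 for both lists with an estimated correlation. MKI67, a marker of proliferating cells (ENSG00000148773, chromosome 10, 128096659 to 128126385, minus strand), fell from 838 ± 22.6 to 389 ± 33.6 CPM. At 100 µg/mL it was at 617 ± 79.9 CPM with Soshiho-tang and at 639.5 ± 16.0 CPM with Okbyeongpung-san, so a level below vehicle was not particular to Soshiho-tang. AURKA, a mitotic kinase, fell by 0.74 ± 0.06, and RRM2, a subunit of ribonucleotide reductase, by 0.54 ± 0.05. Among 20 targets of the tumour suppressor p53, 12 rose and 0 fell (median 0.23; adjusted p = 0.0164 with an estimated correlation). GDF15, a stress-induced secreted factor on that list (ENSG00000130513, chromosome 19, 18374731 to 18389176, plus strand), rose by 1.23 ± 0.10, and TNFRSF10B, a death receptor, by 0.81 ± 0.05. CDKN1A, the cell cycle inhibitor p21, rose by 0.34 ± 0.07 (adjusted p = 0.000715).

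Inflammatory genes and targets of the aryl hydrocarbon receptor were called too. Of 16 inflammatory genes and NF-kappa-B targets 11 rose and 1 fell (median 0.44; adjusted p = 0.0161 with an estimated correlation). CXCL5, a neutrophil chemokine (ENSG00000163735, chromosome 4, 73995642 to 73998779, minus strand), rose from 57.7 ± 3.63 to 152 ± 7.21 CPM, and CXCL2 from 2.39 ± 0.243 to 8.78 ± 1.67 CPM. Among 9 targets of the aryl hydrocarbon receptor 4 rose and 1 fell (median 0.09; adjusted p = 0.0324 with an estimated correlation). CYP1A1, the cytochrome P450 most closely tied to that receptor (ENSG00000140465, chromosome 15, 74719542 to 74725610, minus strand), rose by 1.90 ± 0.20 from 0.875 ± 0.324 CPM, and CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902, minus strand) by 0.83 ± 0.06. Fatty acid oxidation and lipid droplet genes rose in 4 of 10 measured members with 0 fallen (adjusted p = 0.0161 with an estimated correlation), including PLIN2, a lipid droplet coat protein, by 0.95 ± 0.07. The hepatocyte list, fixed as a check for RNA of other cells, held 4 measured genes of 12. FGA and FGB, fibrinogen chains (chromosome 4, 154583126 to 154590766 and 154562956 to 154571086), stood at 190.2 ± 4.83 and 223 ± 8.88 CPM in vehicle and fell by 0.84 ± 0.05 and 0.96 ± 0.07 (list adjusted p = 0.0422 with an estimated correlation).

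The remaining calls for Soshiho-tang at 500 µg/mL included the lists kept as signs of RNA quality. Of 13 mitochondrially encoded messenger RNAs 12 fell (median −0.83), but adjusted p = 0.148 with an estimated correlation. Ribosomal proteins rose in 19 of 25 members (adjusted p = 0.228 with an estimated correlation) and nuclear respiratory chain genes in 12 of 24 (adjusted p = 0.534). Abundant non-coding RNAs rose in 6 of 10 members (median 1.08; adjusted p = 0.0177 with an estimated correlation), such as NEAT1 by 1.17 ± 0.14. Lysosome genes (9 rose and 1 fell of 20) and immediate early genes (10 rose and 1 fell of 20) were called by camera at the preset correlation, with an adjusted p = 0.204 and 0.0831 with an estimated correlation. NRF2 targets, cholesterol genes and fatty acid synthesis genes went both ways, with 7 risen and 6 fallen of 22, 4 and 6 of 24, and 3 and 4 of 14, and were not called. In all, edgeR's quasi-likelihood test called 5783 genes, 2998 higher and 2785 lower, of which 302 and 198 changed at least 2-fold. TGFB2-OT1, a non-coding RNA that overlaps the 3' end of TGFB2 on the same strand, had the largest fold change among the genes the naming rule chose, 3.28 ± 0.60; its assignment is uncertain.

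With the 20 µg/mL libraries of Soshiho-tang in place of vehicle, 3588 genes differed, 1807 higher and 1781 lower. Stress response genes again rose, 18 of 20 with 1 fallen (median 1.11; adjusted p = 5.81e-05 with an estimated correlation). STC2 rose by 2.66 ± 0.06, NIBAN1 by 3.00 ± 0.14, and DDIT3, the stress-induced transcription factor CHOP (ENSG00000175197, chromosome 12, 57516588 to 57521737, minus strand), from 7.40 ± 1.20 to 33.5 ± 5.30 CPM. All 25 mitosis genes and 20 of 24 DNA replication genes fell, and the adjusted p was 0.000317 for both lists with an estimated correlation. Heat shock genes fell in 12 of 13 members (adjusted p = 0.00706 with an estimated correlation). FGA and FGB fell by 1.11 ± 0.05 and 1.16 ± 0.07. Inflammatory genes rose in 11 of 16 members with 1 fallen and immediate early genes in 12 of 20 with 1 fallen, each with an adjusted p = 0.00706 with an estimated correlation. JUN, a subunit of the AP-1 transcription factor, rose by 0.93 ± 0.06.

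Further lists were called against 20 µg/mL, and whether their change differed from that against vehicle was not tested. Fatty acid synthesis genes fell in 8 of 14 members and 0 rose (adjusted p = 0.0217 with an estimated correlation), with FADS2, a fatty acid desaturase, lower by 0.31 ± 0.06. Cholesterol genes fell in 11 of 24 (adjusted p = 0.077 with an estimated correlation). HMGCS1, an early enzyme of cholesterol synthesis (ENSG00000112972, chromosome 5, 43289395 to 43313512, minus strand), fell by 0.41 ± 0.06. Hypoxia targets fell in 7 of 20 members and 1 rose (adjusted p = 0.0192 with an estimated correlation). CYP1A1 gave 0.09 ± 0.15 (adjusted p = 0.738) and CYP1B1 0.11 ± 0.06 (adjusted p = 0.202) between 500 and 20 µg/mL of Soshiho-tang. Their list and the fatty acid oxidation genes, both called against vehicle, were not called against 20 µg/mL. Among signs of RNA quality, the mitochondrially encoded list was not called (median −0.14; camera adjusted p = 0.243), with 1 of 13 members fallen. Abundant non-coding RNAs (3 of 10 rose, among them GAS5 by 0.84 ± 0.08 and NEAT1 by 0.80 ± 0.13) and ribosomal proteins (2 of 25 rose) were called at the preset correlation, with an adjusted p = 0.0721 and 0.655 with an estimated correlation. Of the 3588 genes, 2790 were also called in the same direction against vehicle; the comparisons use the same Soshiho-tang 500 libraries, so part of this overlap comes from the sharing.

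**Figure D2:**
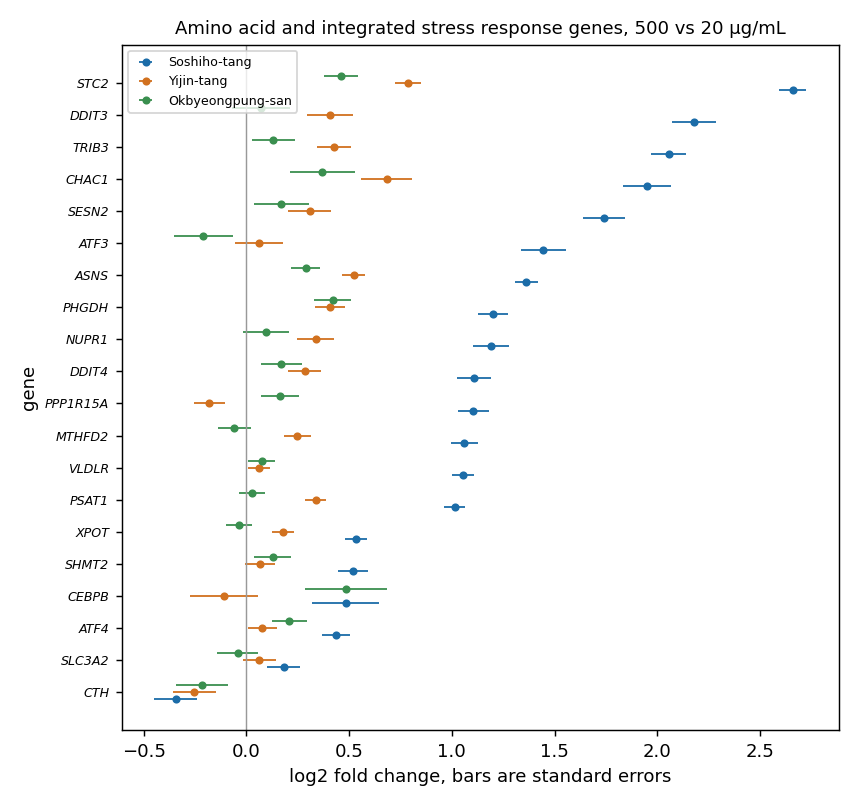
Log2 fold change at 500 against 20 µg/mL (x axis) of the 20 measured genes of the amino acid and integrated stress response (y axis) for Soshiho-tang, Yijin-tang and Okbyeongpung-san; points are estimates and bars are standard errors. The Soshiho-tang points have a median of 1.11, and the Yijin-tang and Okbyeongpung-san points medians of 0.27 and 0.13.

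Yijin-tang at 500 µg/mL raised targets of the aryl hydrocarbon receptor and lipid synthesis genes relative to vehicle. Of 9 receptor targets 5 rose and 0 fell (median 0.29; adjusted p = 0.00608 with an estimated correlation). CYP1A1 went from 0.875 ± 0.324 to 6.04 ± 0.148 CPM, a log2 fold change of 2.78 ± 0.18, CYP1B1 rose by 1.14 ± 0.06, and TIPARP, a poly(ADP-ribose) polymerase induced by the receptor (ENSG00000163659, chromosome 3, 156673235 to 156706770, plus strand), by 1.05 ± 0.08. Cholesterol genes rose in 13 of 24 members and fell in 0 (18 and 0 adjusted over the list alone; adjusted p = 0.0097 with an estimated correlation), and fatty acid synthesis genes in 6 of 14 (adjusted p = 0.00608 with an estimated correlation). SCD, the stearoyl-CoA desaturase (ENSG00000099194, chromosome 10, 100347124 to 100364834, plus strand), rose by 0.56 ± 0.05. Fatty acid oxidation genes rose in 6 of 10 members (adjusted p = 0.00608 with an estimated correlation), PLIN2 by 0.50 ± 0.07.

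Stress response genes rose in 10 of 20 members with Yijin-tang (median 0.21; adjusted p = 0.046 with an estimated correlation), ASNS by 0.62 ± 0.06 and STC2 by 0.73 ± 0.07, and endoplasmic reticulum chaperones in 6 of 16 (adjusted p = 0.0147). NR4A1, an orphan nuclear receptor (ENSG00000123358, chromosome 12, 52022832 to 52059507, plus strand), fell from 36.7 ± 1.09 to 14.2 ± 0.868 CPM, by 1.37 ± 0.08, and NR4A3 by 1.34 ± 0.11. GDF15 and CDKN1A gave 0.14 ± 0.10 and 0.03 ± 0.07 (adjusted p = 0.407 and 0.854). Calls that were lost with an estimated correlation included NRF2 targets (7 of 22 rose, 1 fell; adjusted p = 0.0943), liver X receptor targets (3 of 9 rose; 0.0663), heat shock genes (1 rose and 6 fell of 13; 0.153), DNA replication genes (5 of 24 fell; 0.134), mitosis genes (10 of 25 fell; 0.082) and lysosome genes (5 of 20 rose; 0.139). Glycolysis enzymes (5 rose and 1 fell of 17; 0.445), metallothioneins (1 of 4 rose; 0.126), mucins (4 of 9 fell; 0.126) and the hepatocyte list (2 of 4 fell; 0.0943) were lost in the same way. MUC5AC, a secreted airway mucin, fell by 0.75 ± 0.11 from 327.5 CPM in vehicle. At 100 µg/mL it was already at 185 CPM with Yijin-tang, at 220 CPM with Okbyeongpung-san and at 227 CPM with Soshiho-tang. HMOX1, the NRF2 target haem oxygenase 1 (ENSG00000100292, chromosome 22, 35380361 to 35394214, plus strand), rose by 0.57 ± 0.06. Beside these, 11 of 13 mitochondrially encoded messenger RNAs fell (median −0.71; adjusted p = 0.082 with an estimated correlation), 16 of 25 ribosomal proteins and 12 of 24 respiratory chain genes rose (adjusted p = 0.126 for both), and abundant non-coding RNAs rose in 4 of 10 members with 1 fallen (adjusted p = 0.046 with an estimated correlation).

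In all, 2737 genes differed between Yijin-tang at 500 µg/mL and vehicle, 1417 higher and 1320 lower. The count was 1670 and 1687 without vehicle replicates 2 and 3, 1668 and 1613 without Yijin-tang 500 replicates 1 and 3, and 4262 with only the 2 groups in the fit.

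Against its own 20 µg/mL libraries, Yijin-tang at 500 µg/mL changed 123 genes, 50 higher and 73 lower. CYP1A1 rose by 1.88 ± 0.15, CYP1B1 by 0.97 ± 0.06, TIPARP by 0.91 ± 0.07 and AHRR, a repressor of the same receptor (ENSG00000063438, chromosome 5, 304176 to 438291, plus strand), by 0.69 ± 0.11. The receptor list rose in 4 of 9 members (median 0.36; adjusted p = 1.45e-06 with an estimated correlation). Stress response genes rose in 6 of 20 (12 rose and 2 fell adjusted over the list alone; median 0.27; adjusted p = 0.00128 with an estimated correlation), with STC2 higher by 0.79 ± 0.06 and ASNS by 0.52 ± 0.06. NR4A3 fell by 1.20 ± 0.10, NR4A1 by 1.13 ± 0.08, FGA by 0.65 ± 0.05 and FGB by 0.64 ± 0.07 (hepatocyte list adjusted p = 0.00128 with an estimated correlation). GREM1, a secreted BMP antagonist, rose by 0.86 ± 0.11, and STC1, a secreted stanniocalcin, fell by 0.67 ± 0.10. Fatty acid oxidation genes, called against vehicle, had no camera call against 20 µg/mL. Cholesterol genes had a median of 0.08 with 0 of 24 past the test (camera adjusted p = 0.000562; adjusted p = 0.0908 with an estimated correlation). Fatty acid synthesis genes had 1 of 14 risen, SCD (adjusted p = 0.00809 for the list with an estimated correlation); the SCD call (0.23 ± 0.05, adjusted p = 0.031) was lost without Yijin-tang 500 replicates 2 and 3 (adjusted p = 0.224 and 0.0814), without Yijin-tang 20 replicates 1 and 3 (0.0941 and 0.184) and with only the 2 groups in the fit (0.407). The count of 123 was 77, 77 and 69 without Yijin-tang 500 replicates 1, 2 and 3, 76 without Yijin-tang 20 replicate 2, 54 with only the 2 groups in the fit, 241 without a filter on low counts and 311 with a length and GC offset.

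**Figure D3:**
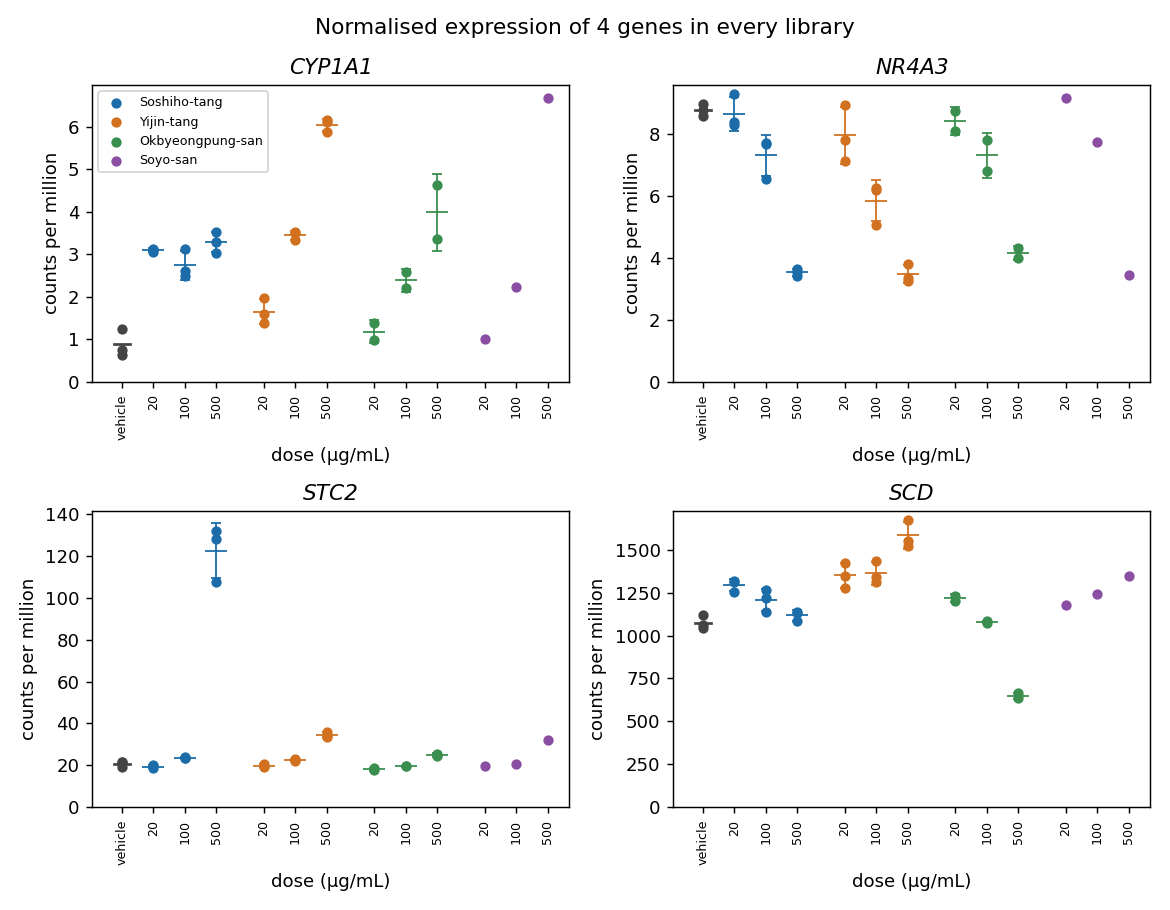
CPM of CYP1A1, NR4A3, STC2 and SCD (y axes) by dose in µg/mL (x axis, with vehicle at 0) for each extract; points are libraries, bars are group means with standard deviations, and Soyo-san has 1 library per dose. CYP1A1 went from 0.875 in vehicle to 6.04 with Yijin-tang at 500 µg/mL, and STC2 from 20.7 to 122 with Soshiho-tang at 500 µg/mL.

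Okbyeongpung-san at 500 µg/mL lowered lipid synthesis genes relative to vehicle. Of 14 fatty acid synthesis genes 9 fell and 0 rose (median −0.23; adjusted p = 0.00197 with an estimated correlation), and of 24 cholesterol genes 11 fell and 1 rose (16 and 2 adjusted over the list alone; median −0.24; adjusted p = 0.00921). SCD fell from 1075 ± 42.3 (n = 3) to 649 ± 19.0 CPM (n = 2), by 0.73 ± 0.06. INSIG1, a sterol sensor of the endoplasmic reticulum (ENSG00000186480, chromosome 7, 155297776 to 155310235, plus strand), fell by 0.86 ± 0.08 and HMGCS1 by 0.65 ± 0.07. Fatty acid oxidation genes rose in 5 of 10 members (median 0.32; adjusted p = 0.00197 with an estimated correlation), with CPT1A, the entry enzyme of mitochondrial fatty acid oxidation, higher by 0.55 ± 0.08. NRF2 targets rose in 8 of 22 members with 1 fallen (adjusted p = 0.0303 with an estimated correlation), HMOX1 by 0.90 ± 0.07. CYP1A1 rose by 2.19 ± 0.20 and CYP1B1 by 0.79 ± 0.07, and their list rose in 4 of 9 members with 1 fallen (adjusted p = 0.0495 with an estimated correlation).

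Mitosis genes fell in 15 of 25 members with Okbyeongpung-san (median −0.26; adjusted p = 0.0196 with an estimated correlation), KIF23 by 0.31 ± 0.05, and TGF-beta and mesenchymal genes in 8 of 21 with 2 risen (adjusted p = 0.0377), CDH2, N-cadherin, by 0.41 ± 0.06. NR4A3 fell by 1.08 ± 0.12. Lysosome genes rose in 8 of 20 members with 1 fallen (adjusted p = 0.0439 with an estimated correlation), CTSL, a lysosomal protease, by 0.62 ± 0.07. Stress response genes (5 of 20 rose), heat shock genes (5 of 13 fell), metallothioneins (1 of 4 rose), ribosomal proteins (10 of 25 rose) and respiratory chain genes (9 of 24 rose) were called at the preset correlation, with an adjusted p = 0.265, 0.191, 0.231, 0.231 and 0.317 with an estimated correlation. Mitochondrially encoded messenger RNAs fell in 7 of 13 members (median −0.53; adjusted p = 0.203 with an estimated correlation), and abundant non-coding RNAs rose in 6 of 10 with 1 fallen (adjusted p = 0.0319). The test called 2610 genes, 1256 higher and 1354 lower. The count was 1224 without replicate 2 of Okbyeongpung-san 500, the library described above, and 4321 without replicate 3; 1469, 1521 and 1478 without vehicle replicates 1, 2 and 3; and 436 with only the 2 groups in the fit. A fit that leaves 1 library in a group assumes that it varies like the other groups. In the main fit the SE and adjusted p of Okbyeongpung-san at 500 µg/mL rest on a spread shared with the other groups. Its own libraries lay further apart than any other replicates, with a chi-square per degree of freedom of 42.4.

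Between 500 and 20 µg/mL of Okbyeongpung-san, a comparison added after the data were seen, lipid synthesis genes fell again. SCD fell by 0.91 ± 0.06, HMGCS1 by 0.76 ± 0.08, INSIG1 by 0.75 ± 0.08, and STARD4, a sterol transporter, by 0.71 ± 0.09. Fatty acid synthesis genes fell in 7 of 14 members (median −0.28; adjusted p = 1.84e-05 with an estimated correlation) and cholesterol genes in 10 of 24 (18 adjusted over the list alone; median −0.32; adjusted p = 0.000105). CYP1A1 rose by 1.77 ± 0.21, CYP1B1 by 0.72 ± 0.08 and HMOX1 by 0.83 ± 0.07. NRF2 targets, TGF-beta genes and abundant non-coding RNAs, called as lists against vehicle, were not called between these doses. The list of CYP1A1 rose in 4 of 9 members (adjusted p = 0.000798 with an estimated correlation), and 1 of 25 mitosis genes fell (14 adjusted over the list alone; adjusted p = 0.0409 with an estimated correlation). The mitochondrially encoded list had a median of 0.32 with 0 of 13 members past the test (adjusted p = 0.539 with an estimated correlation), and replicate 2 held the higher mitochondrial share. Respiratory chain genes (median −0.12; 0 of 24 fell) and the hepatocyte list (median −0.34; 2 of 4 fell, FGA by 0.42 ± 0.06) were called at the preset correlation, with an adjusted p = 0.539 and 0.251 with an estimated correlation. So were stress response, lysosome and immediate early genes (3 of 20 rose in each; 0.265, 0.251 and 0.0681) and fatty acid oxidation genes (0 of 10 rose; 0.0681). The test called 278 genes, 171 higher and 107 lower, and with only the 2 groups in the fit edgeR called 0 (857 at an unadjusted p under 0.05), which ended the call of each gene named in this paragraph; DESeq2 with all groups called 526. The count was 44 and 4054 without Okbyeongpung-san 500 replicates 2 and 3, 61 and 39 without Okbyeongpung-san 20 replicates 2 and 3, 185 when all libraries were thinned to the lowest total, and 889 without a filter on low counts.

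**Figure D4:**
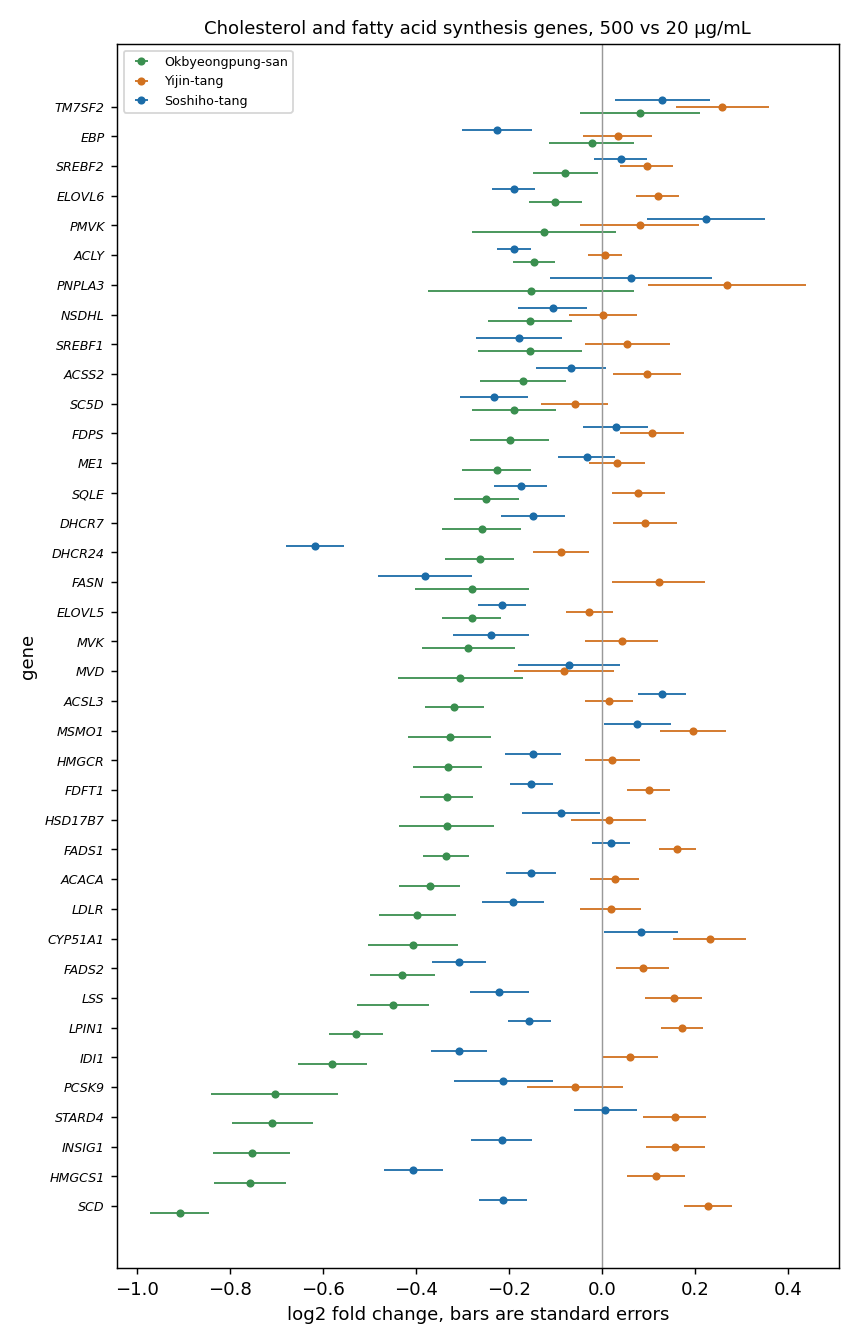
Log2 fold change at 500 against 20 µg/mL (x axis) of cholesterol and fatty acid synthesis genes (y axis) for Soshiho-tang, Yijin-tang and Okbyeongpung-san; points are estimates and bars are standard errors. The cholesterol list has a median of −0.32 with Okbyeongpung-san, 0.08 with Yijin-tang and −0.15 with Soshiho-tang.

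Direct comparison of Soshiho-tang with Yijin-tang at 500 µg/mL asks where the extracts differ. Stress response genes were higher with Soshiho-tang in 18 of 20 members (median 0.83; adjusted p = 2.68e-05 with an estimated correlation). NIBAN1 was higher by 2.28 ± 0.13, STC2 by 1.84 ± 0.06, DDIT3 by 1.74 ± 0.10 and CHAC1, a glutathione-degrading enzyme, by 1.45 ± 0.11. p53 targets were higher in 11 of 20 members, inflammatory genes in 11 of 16 with 1 lower, immediate early genes in 9 of 20 and endoplasmic reticulum chaperones in 6 of 16 with 1 lower (adjusted p = 0.00391, 0.00319, 0.0031 and 0.00437 with an estimated correlation). All 25 mitosis genes and 18 of 24 DNA replication genes were lower with Soshiho-tang (adjusted p = 0.000201 and 0.000218). Cholesterol genes were lower in 12 of 24 members and fatty acid synthesis genes in 9 of 14 (adjusted p = 0.00139 and 0.000387 with an estimated correlation), with SCD lower by 0.50 ± 0.05. CYP1A1 was lower with Soshiho-tang by 0.87 ± 0.14, at 3.28 ± 0.242 against 6.04 ± 0.148 CPM. Heat shock genes (11 of 13 lower), hypoxia targets (5 of 20 lower, 1 higher) and the hepatocyte list (2 of 4 lower) were also called, with an adjusted p = 0.00319, 0.00591 and 0.0402 with an estimated correlation. Glycolysis enzymes (8 of 17 lower), respiratory chain genes (2 of 24 lower) and abundant non-coding RNAs (2 of 10 higher) lost their call, with an adjusted p = 0.142, 0.581 and 0.0627. The mitochondrially encoded list had a median of −0.10 and was not called (camera adjusted p = 0.399). The test called 2200 genes, 1101 higher and 1099 lower; the count was 1361 without Soshiho-tang 500 replicate 2 and 3569 with a length and GC offset.

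The responses of both extracts were also compared as a whole, with the vehicle libraries shared between them. Across 17459 genes, which are not independent replicates, log2 fold changes against vehicle had a Pearson correlation of 0.783, while simulated unchanged groups that share their controls gave 0.586 ± 0.0157 (SD of 20 simulations). The covariance was 0.244, with 0.0686 in the simulations. In the simulations the vehicle libraries did not stand apart from the treated ones, as the real vehicle libraries do. Values above the simulated ones can therefore come from that departure, and do not show a response shared by the extracts. Genes higher in both numbered 1055 and genes lower in both 1067; no value without a change is given for these counts, because the vehicle libraries are shared. With fold changes of 500 against 20 µg/mL, which share no library, the correlation was 0.263.

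Differences between the dose effects were tested as well, after the data were seen. The change from 20 to 500 µg/mL was larger with Soshiho-tang than with Yijin-tang for STC2 by 1.87 ± 0.09 and DDIT3 by 1.77 ± 0.15, and larger than with Okbyeongpung-san for these genes by 2.20 ± 0.10 and 2.11 ± 0.18. Stress response genes differed in 17 of 20 members in the first case and 16 of 20 in the second (adjusted p = 1.09e-05 and 5.84e-05 with an estimated correlation). Between Yijin-tang and Okbyeongpung-san, SCD differed by 1.14 ± 0.08 (adjusted p = 1.18e-08), INSIG1 by 0.91 ± 0.10 and HMGCS1 by 0.87 ± 0.10. The SE and adjusted p of each difference with Okbyeongpung-san rest on a spread shared with the other groups. Its own 2 libraries at 500 µg/mL lay further apart than any other replicates, with a chi-square per degree of freedom of 42.4. Cholesterol genes differed in 7 of 24 members and fatty acid synthesis genes in 4 of 14, each higher with Yijin-tang (adjusted p = 2.96e-05 and 2.78e-06 with an estimated correlation). Signs of RNA quality differed as well. With Yijin-tang minus Okbyeongpung-san, mitochondrially encoded messenger RNAs had a median of −0.41, respiratory chain genes 0.13 and ribosomal proteins 0.09, all called at the preset correlation (adjusted p = 0.427, 0.495 and 0.693 with an estimated correlation). With Soshiho-tang minus Okbyeongpung-san, abundant non-coding RNAs had a median of 0.45 (adjusted p = 0.0342 with an estimated correlation), mitochondrially encoded messenger RNAs −0.49 (0.419) and ribosomal proteins 0.20 (0.536). With Soshiho-tang minus Yijin-tang, abundant non-coding RNAs had a median of 0.19 (0.0758). The hepatocyte list had 2 of 4 members lower with Soshiho-tang than with Yijin-tang (median −0.45, adjusted p = 0.04 with an estimated correlation). It also had 2 of 4 lower than with Okbyeongpung-san (−0.73, 0.0213), and a median of −0.25 with Yijin-tang minus Okbyeongpung-san (0.291). The list was fixed as a check for RNA of other cells. Yet FGA and FGB, neighbours on chromosome 4, were already at 229 and 257 CPM with Soshiho-tang at 20 µg/mL. APOH and SERPINA1 were at 4.80 and 0.815 CPM there. These differences therefore cannot be read as a sign of RNA from other cells.

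At 100 and 20 µg/mL the calls against vehicle included mitochondrial, ribosomal and non-coding transcripts. MT-ATP8 fell by 1.87 ± 0.31 with both lower doses of Soshiho-tang, by 2.00 ± 0.31 and 1.93 ± 0.31 with Yijin-tang at 100 and 20 µg/mL, and by 2.27 ± 0.36 and 2.02 ± 0.36 with Okbyeongpung-san. Mitochondrially encoded messenger RNAs fell in 9 to 12 of 13 members in these 6 comparisons, and the adjusted p with an estimated correlation was 0.0654 to 0.158. Ribosomal proteins rose in 11 to 16 of 25 members (0.0936 to 0.192) and respiratory chain genes in 9 to 16 of 24 (0.0936 to 0.185). TGFB2-OT1, RN7SL1 and RN7SL2, a signal recognition particle RNA with near-identical copies, FMC1, which overlaps the readthrough gene FMC1-LUC7L2, and EIF3CL, a near-copy of EIF3C, were among the genes with the largest increases, and their assignment is uncertain.

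CYP1A1 nevertheless rose by 1.64 ± 0.20 and 1.81 ± 0.20 with Soshiho-tang at 100 and 20 µg/mL, by 1.97 ± 0.20 and 0.90 ± 0.21 with Yijin-tang and by 1.44 ± 0.22 with Okbyeongpung-san at 100 µg/mL; at 20 µg/mL of Okbyeongpung-san it gave 0.42 ± 0.25 (adjusted p = 0.336). ASNS rose by 0.33 ± 0.06 with Soshiho-tang at 100 µg/mL (adjusted p = 0.00124). Fatty acid oxidation genes rose with Soshiho-tang at 100 µg/mL (3 of 10) and with Okbyeongpung-san at 100 and 20 µg/mL (2 of 10 in each), with an adjusted p = 0.0165, 0.0481 and 0.0321 with an estimated correlation. Abundant non-coding RNAs rose in 6 of 10 members with 1 fallen in both lower doses of Okbyeongpung-san (adjusted p = 0.0481 and 0.025), and TGF-beta genes fell in 6 of 21 at 20 µg/mL (adjusted p = 0.0321). Of the camera calls at 100 and 20 µg/mL, 15 and 21 with Soshiho-tang, 18 and 18 with Yijin-tang and 12 and 11 with Okbyeongpung-san, these 6 were the ones that held with an estimated correlation.

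Soshiho-tang at 100 and 20 µg/mL differed from vehicle in 1879 and 1401 genes. Without vehicle replicates 1, 2 and 3 the counts were 974, 906 and 852 at 100 µg/mL and 714, 617 and 582 at 20 µg/mL, and without Soshiho-tang replicates 1 and 2 of the dose they were 681 and 926, and 512 and 661. At 20 µg/mL the count was 2993 with only the 2 groups in the fit. Yijin-tang gave 2568 and 1789 genes. Its counts without vehicle replicates 1, 2 and 3 were 1676, 1579 and 1552 at 100 µg/mL and 1061, 892 and 876 at 20 µg/mL, and without Yijin-tang replicate 3 of the dose 1213 and 551. Okbyeongpung-san gave 1656 and 1773 genes, with 866 and 940 at 100 µg/mL and 952 and 1044 at 20 µg/mL without vehicle replicates 2 and 3. Without Okbyeongpung-san replicates 2 and 3 of the dose the counts were 190 and 471, and 468 and 259. With only the 2 groups in the fit they were 4573 and 4647, and with 1 surrogate variable 697 and 794.

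Set against each other, the lower doses differed in few single genes, while some lists were called. Between 100 and 20 µg/mL edgeR called 0 genes for Soshiho-tang (422 at an unadjusted p under 0.05; 0 by DESeq2), 0 for Okbyeongpung-san (295 unadjusted; 0 by DESeq2) and 4 for Yijin-tang. Those 4 were CYP1A1, higher at 100 µg/mL by 1.07 ± 0.16, CYP1B1 by 0.52 ± 0.06, TIPARP by 0.42 ± 0.08, and NR4A1, lower by 0.46 ± 0.08. The Yijin-tang count was 0 with only the 2 groups in the fit (257 unadjusted), 7 by DESeq2, 2 and 1 without Yijin-tang 100 replicates 1 and 2, and 1, 1 and 2 without Yijin-tang 20 replicates 1, 2 and 3. At 100 µg/mL Soshiho-tang and Yijin-tang differed in 0 genes by edgeR (672 unadjusted; 3 by DESeq2), and at 20 µg/mL in 1, CYP1B1, higher with Soshiho-tang by 0.54 ± 0.06 (adjusted p = 0.000125). List calls that held with an estimated correlation, at small medians, were these. Between 100 and 20 µg/mL of Soshiho-tang they were stress response genes (median 0.09; 0.0434), fatty acid synthesis genes (−0.06; 0.0434) and aryl hydrocarbon receptor targets (−0.15; 0.0455). With Yijin-tang they were receptor targets (0.09; 0.000197), the hepatocyte list (−0.23; 0.0306), interferon targets (0.15; 0.0341) and ribosome biogenesis genes (0.04; 0.0373), and with Okbyeongpung-san receptor targets (0.08; 0.00348). Between Soshiho-tang and Yijin-tang they were fatty acid synthesis genes at 100 µg/mL (−0.08; 0.0385) and receptor targets at 20 µg/mL (0.13; 4.27e-06).

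Soyo-san had 1 library per dose, all titled batch D, so its values stand with no test. At 500 µg/mL CYP1A1 was at 6.68 CPM, 7.68-fold the vehicle mean, and CYP1B1 at 209.8 CPM, 2.07-fold. ASNS and GDF15 were 1.52-fold and 1.43-fold the vehicle mean. Of 10997 genes with a mean of at least 5 CPM, 16 were at least 2-fold higher than the vehicle mean and 23 at least 2-fold lower. Those outside the vehicle range included BEST1, a chloride channel, 2.85-fold higher, and UAP1L1, 2.11-fold higher. In the lower direction they included TUBA1B-AS1, at 0.0327 CPM, MT-ATP8 and MT-ND6. BEST1 is also among the 391 genes called in all 9 comparisons of the other extracts with vehicle. Its log2 difference from the Soyo-san library at 20 µg/mL was 0.31, and that of UAP1L1 was 0.94. Against the 20 µg/mL library of Soyo-san, 8 genes were at least 2-fold higher and 6 lower at 500 µg/mL, among them AHRR with a log2 difference of 1.23 and NR4A3 with −1.41, both named after their values were seen. The median log2 difference of the stress response genes was 0.25 against vehicle and 0.24 against 20 µg/mL, each at percentile 100 of 10000 random lists matched on expression. Other lists lay as far out. Against vehicle, percentile 100 also held for NRF2 targets (0.10), cholesterol genes (0.18), ribosomal proteins (0.18), respiratory chain genes (0.16) and abundant non-coding RNAs (0.34), and percentile 0 for mitochondrially encoded messenger RNAs (−0.64) and TGF-beta genes (−0.22). Against 20 µg/mL the mitochondrially encoded list was at percentile 100 (0.19). Receptor targets of the CYP1A1 list had a median of 0.21 against 20 µg/mL.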

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

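Chosen after the result was seen were the tests of the size ratio between 500 and 20 µg/mL, of the spread of positions and of the median response ratio in Okbyeongpung-san 500 replicate 2, and of the stress response against 20 µg/mL; the other tests were written before their result was seen.

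A difference between groups brought 4 results here. Between Soshiho-tang and Yijin-tang at 500 µg/mL 2200 genes differed in the direct test. The change from 20 to 500 µg/mL differed between Soshiho-tang and Yijin-tang in 705 genes, 397 higher and 308 lower with Soshiho-tang, between Soshiho-tang and Okbyeongpung-san in 1224 genes, 572 higher and 652 lower, and between Yijin-tang and Okbyeongpung-san in 28 genes, 15 higher and 13 lower. Each is a test of the difference itself. The tests with Okbyeongpung-san use its 2 libraries at 500 µg/mL, which lay further apart than any other replicates. Their spread was shared with the other groups, and no other setting is given here for the differences of dose effects.

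The first pattern is that vehicle libraries lie apart from every treated library, with 391 genes called in all 9 comparisons with vehicle. Their lower depth is argued against, since 305 of these genes (78.0%) were called again in all 9 after every library was thinned to the lowest total. A trend over transcript length and GC is argued against as the whole cause, since 290 (74.2%) were called again in all 9 with an offset for it, and their median size went from 0.413 to 0.359. An effect shared by the 3 extracts stays open: the median size of these genes at 500 over that at 20 µg/mL was 1.32 with Soshiho-tang, 1.09 with Yijin-tang and 0.881 with Okbyeongpung-san, and a saturated effect or a separate preparation of the vehicle libraries may both give values near 1. These cannot be told apart here, as no other untreated library was analysed. The labels do not say whether the vehicle libraries were prepared with the treated ones. The batch title does not separate them, since all 3 vehicle libraries carry batch E, as do all Soshiho-tang and Yijin-tang libraries. The library names do separate them: those of vehicle share a prefix that no treated library carries. Prefixes also differ between some extracts, and what they stand for is not stated.

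The second pattern is Okbyeongpung-san 500 replicate 2, which lies toward the vehicle libraries relative to replicate 3. A vehicle library under this label is argued against, since its slope on the response of replicate 3 against the 20 µg/mL libraries was 0.372 over 43 genes, with vehicle slopes of −0.0753 to 0.0458. Higher depth is argued against, since its share along the axis to vehicle was 33.7% at full depth and 39.3% after thinning, with −5.13% to 25.0% in the other treated libraries. Vehicle RNA mixed into the library stays open, and the tests of it do not all point the same way. The slope had a bootstrap interval of 0.0803 to 1.12, which holds the 0.663 that mixing would leave. Another 2 tests, added after this left the question open, point against it. The first placed 26 genes of the first pattern, with a mean log2 size of at least 1, between the other libraries of the extract and the vehicle mean. Mixing would give them a shared position, but 7 lay under 25% of the way and 6 over 75%. Their SD was 34.7%, only a little above the 32.8% of the highest other library of the extract. The median response ratio, seen before the test was written, was 0.967 with an interval of 0.858 to 1.12. No biological explanation was tested, as replicates 2 and 3 also differ in their batch title.

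The third pattern is the rise of stress response genes with Soshiho-tang at 500 µg/mL, a median log2 fold change of 1.14. The difference between vehicle and treated libraries is argued against, since the median against the 20 µg/mL libraries was 1.11, as is transcript length and GC, with a median of 1.17 under the offset. Dependence on 1 library is argued against too, since the lowest median with 1 of the 3 Soshiho-tang 500 libraries left out was 1.11. A response of the cells to this extract at 500 µg/mL is a hypothesis that remains, found and tested on the same data.

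The 6 libraries of a comparison can be split into groups of 3 in 10 ways, the real split among them, which is too few for a share under 0.05. In each of the 9 comparisons with 3 libraries per group, 1 split, the real split, gave as many genes as the real value. The real values were 5783, 1879 and 1401 for Soshiho-tang at 500, 100 and 20 µg/mL against vehicle, 2737 and 1789 for Yijin-tang at 500 and 20 µg/mL against vehicle, 2200 for Soshiho-tang against Yijin-tang, and 3588 and 123 for Soshiho-tang and Yijin-tang at 500 against 20 µg/mL, with 0 as the highest other value. For Yijin-tang at 100 µg/mL against vehicle the real value was 2568 and the highest other 1.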

How the results depend on the processing

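Chosen after the data were seen were the use of 20 µg/mL libraries in place of vehicle (except that 500 against 20 µg/mL of Soshiho-tang and Yijin-tang were planned comparisons), every comparison of Okbyeongpung-san at 500 against 20, the surrogate variable, the length and GC offset and the thinning; the other alternatives were planned. No named gene that was called changed its direction in any alternative run. Fewer libraries or groups in a fit leave less information on the spread, but counts rose in some of these fits and fell in others. No cause was tested for the changes below. The main fit shares its estimate of spread between groups, while the chi-square per degree of freedom between replicates ran from 2.07 to 42.4. Lower depth, tried by thinning, lowered each count of genes against vehicle, between extracts at 500 µg/mL and between 500 and 20 µg/mL, by more than 1.5 times only for Okbyeongpung-san at 500 against 20.

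With 20 µg/mL of the same extract in place of vehicle, 500 and 100 µg/mL gave 3588 and 0 genes for Soshiho-tang (422 for the latter at an unadjusted p under 0.05 by edgeR, 0 by DESeq2), 123 and 4 for Yijin-tang, and 278 and 0 for Okbyeongpung-san (295 unadjusted, 0 by DESeq2). With 20 µg/mL of the other extracts in its place, edgeR called at 20 µg/mL 3 genes for Soshiho-tang, 0 for Yijin-tang (540 unadjusted) and 0 for Okbyeongpung-san (876 unadjusted).

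With only the 2 groups in the fit the counts against vehicle were 2993 for Soshiho-tang 20, 4262 for Yijin-tang 500, and 436, 4573 and 4647 for Okbyeongpung-san 500, 100 and 20; at 500 against 20 they were 54 for Yijin-tang and 0 for Okbyeongpung-san (857 unadjusted by edgeR). Without a filter these dose comparisons gave 241 and 889 genes, and DESeq2 gave 526 for Okbyeongpung-san. A surrogate variable gave 697 and 794 genes for Okbyeongpung-san 100 and 20 against vehicle. The length and GC offset gave 3569 for Soshiho-tang against Yijin-tang and 311 for Yijin-tang 500 against 20, and thinning gave 185 for Okbyeongpung-san 500 against 20.

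Leaving out 1 library gave, against vehicle, 681 to 2137 and 512 to 1108 genes for Soshiho-tang 100 and 20, 1613 to 2403, 1213 to 2405 and 551 to 2070 for Yijin-tang 500, 100 and 20, and 1224 to 4321, 190 to 1107 and 259 to 1183 for Okbyeongpung-san 500, 100 and 20. It gave 1361 to 1811 for Soshiho-tang against Yijin-tang, and 69 to 104 and 39 to 4054 for Yijin-tang and Okbyeongpung-san at 500 against 20.

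Of 188 list calls in the 12 planned comparisons 60 held with an estimated correlation. In these comparisons fry called 241 lists, but of the camera calls it held 20 of 21 for Soshiho-tang 20 and 17 of 18 for Yijin-tang 20 against vehicle, 14 of 15 for Soshiho-tang against Yijin-tang and for Soshiho-tang 500 against 20, and 10 of 12 for Yijin-tang 500 against 20. In the added comparisons it held 9 of 11 for Okbyeongpung-san 500 against 20, 2 of 6, 3 of 10 and 1 of 4 for 100 against 20 of Soshiho-tang, Yijin-tang and Okbyeongpung-san, and 1 of 10 for Soshiho-tang against Yijin-tang at 100 µg/mL. The similarity of 0.783 was 0.638 without a filter, 0.742 with a surrogate variable, 0.763 when thinned, 0.263 with 20 µg/mL in place of vehicle and 0.717 to 0.816 with 1 library left out. The 39 Soyo-san genes at 500 µg/mL became 132 at a mean of at least 1 CPM and 14 against the Soyo-san 20 library.

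The labels do not state that libraries with the same replicate number belong together. Library names of Soshiho-tang and Yijin-tang do share a prefix within each replicate number, and what it stands for is not stated. The main fit did not use this grouping. As a hint from the data, 16 of 27 correlated best with a library of their own number, so some did and not every library did; for Okbyeongpung-san the number goes with the batch title. With a replicate block the counts were 6026, 2088 and 1558 for Soshiho-tang, 2972, 2848 and 2067 for Yijin-tang and 3080, 1900 and 2062 for Okbyeongpung-san against vehicle, and 2393, 3798 and 151 for the other 3 planned comparisons. Of the list calls it held 20 of 21 for Soshiho-tang 20 against vehicle, 14 of 15 for Soshiho-tang against Yijin-tang and 10 of 12 for Yijin-tang 500 against 20, and all calls of the other comparisons.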

Other observations

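The levels of NR4A3 and FGB in all extracts and the tests of genes shared between extracts were chosen after the data were seen, and no explanation was tested for them. The 9 lists given first had no camera call in the comparisons of 500 µg/mL with vehicle. With Soshiho-tang, Yijin-tang and Okbyeongpung-san at 500 µg/mL, glucocorticoid targets had 5, 2 and 2 of 14 measured members risen and 5, 4 and 1 fallen, and epithelial genes 4, 2 and 2 of 17 risen and 4, 1 and 2 fallen. FOXO targets had 3, 3 and 1 of 17 risen and 4, 1 and 0 fallen, ribosome biogenesis genes 5, 2 and 1 of 20 risen and 4, 4 and 4 fallen, and interferon targets 3, 2 and 2 of 16 risen and 0 fallen. Histones had 2, 2 and 0 of 12 risen and 1, 1 and 0 fallen, and xenobiotic conjugation genes 1, 1 and 1 of 9 risen and 2, 1 and 0 fallen. Alveolar genes, with 5 measured members, had 2 risen and 1 fallen with Soshiho-tang and 0 with the other extracts, and fibroblast markers, also with 5, had 1 fallen with Soshiho-tang and 0 in the rest. Soshiho-tang at 500 µg/mL left liver X receptor targets (2 risen and 1 fallen of 9), hypoxia targets (3 and 5 of 20), glycolysis enzymes (4 and 7 of 17), metallothioneins (1 and 0 of 4), mucins (0 and 2 of 9) and TGF-beta genes (3 and 8 of 21) without a call.

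NR4A3, chosen here after its values were seen for all 4 extracts, went from 8.80 CPM in vehicle to 8.66, 7.32 and 3.54 CPM with Soshiho-tang at 20, 100 and 500 µg/mL. It was at 7.97, 5.86 and 3.47 CPM with Yijin-tang, 8.43, 7.33 and 4.17 CPM with Okbyeongpung-san, and 9.18, 7.76 and 3.44 CPM in the single libraries of Soyo-san. FGB, chosen in the same way, was at 223 CPM in vehicle and at 257, 242 and 115 CPM with Soshiho-tang, 252, 212 and 161 CPM with Yijin-tang, 241, 216 and 184 CPM with Okbyeongpung-san and 235, 214 and 158 CPM in the Soyo-san libraries.

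Genes called at 500 against 20 µg/mL were partly shared between extracts. Soshiho-tang and Yijin-tang shared 40 higher and 60 lower genes, with 5.18 and 7.45 for independent lists, and 6 genes were opposite. Soshiho-tang and Okbyeongpung-san shared 64 higher and 75 lower, with 17.7 and 10.9 for independent lists and 16 opposite, and Yijin-tang and Okbyeongpung-san 14 and 23, with 0.490 and 0.447 and 1 opposite.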
